A study of Caenorhabditis elegans with 4 samples.

How the data were processed

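Binding of NHR-6, a nuclear hormone receptor of Caenorhabditis elegans, was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in hermaphrodite larvae of the second stage (L2). Per the labels' protocols, worms carrying a transgene that encodes NHR-6 fused to enhanced green fluorescent protein (EGFP) and epitope tags were grown in liquid culture at 20 °C, crosslinked with 2% formaldehyde and sonicated. Chromatin was precipitated with an affinity-purified goat antibody against GFP, and DNA was size-selected on a gel and made into Illumina libraries. The immunoprecipitation protocol speaks of embryos, and the stage is taken here from the sample labels, which give L2. The 4 libraries form 2 groups, precipitated DNA (ChIP DNA, 2 libraries) and input DNA (2 libraries). Each of the 2 replicate numbers covers 1 library of each group.

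The deposited data used here are 1 list of binding regions, which its title describes as combined; it is taken to cover both replicates. Per the file headers, the list is in GFF3 format on genome build WormBase WS180, and its source column names PeakSeq, a peak caller that compares ChIP with input reads, as the origin of every region. The authors gave each region a start, an end and a q-value, and no read count, fold enrichment, summit or value per library. All deposited q-values were under 0.01. The read length, aligner, peak caller version and settings, and the way the replicates were combined are not given in the sources used here. The sequencing depth of each library is therefore unknown, no replicate error could be computed, and a region missed for lack of reads cannot be told from an unbound one. The calls also rest on the authors' scaling of input to ChIP, which could not be varied here.

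From the deposited positions and q-values, region widths, midpoints, and −log10 of the q-value were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The q-value is the peak caller's own value and was used only within this list, to rank regions, to compare their strength between sets and with width, and, multiplied by rank, to find shared values. A strong region below means one with a small q-value. This is a measure of significance and not of occupancy, for which no read count or fold enrichment was given. The 1 mitochondrial region was left out of the comparisons, which leaves 1208 nuclear regions. Chromosome lengths of build WS180 were not given, so each chromosome was taken to run from its first base to the end of its last region.

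Counts per chromosome were compared with the share of total length by exact two-sided binomial tests with Benjamini-Hochberg adjustment over the 6 chromosomes, and jointly by 100000 multinomial draws. The share of midpoints in the central segment, the middle 33.3% of each chromosome by length, was tested by an exact binomial test, adjusted over the pair of autosomes and X. The share of regions with another midpoint within 5 kb was compared with 10000 uniform placements of the same number of regions per chromosome. Differences in median −log10 q were tested by permutation with 100000 resamples. Exact Clopper-Pearson or Poisson intervals at 95% cover counting error only. Neighbouring regions are not independent, so 500 kb bins were also shuffled between chromosomes and region sets rotated around each chromosome. The statistics were tested on simulated lists of 1208 regions. A chromosome I made 1.5 times as dense as the others was estimated at 1.50 times their density on average and called in 100% of 100 lists. A uniform list was called in 1% for chromosome I and 6% for the central segment, the latter by unadjusted p. Regions in these lists were placed independently of one another, so the rates do not hold for regions that cluster. The chromosome ratios to length reported below are another measure, because their expected number is taken over all chromosomes, including the one tested. They lie closer to 1 than ratios to the other chromosomes, and their size was not estimated in the simulations.

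The rule for named items was set before the data were examined: the 20 nuclear regions with the smallest q-values, with the nearest gene start where an annotation of the same build could be used. The only gene table used here is of assembly WBcel235, a later build than WS180, so regions were named by position alone. For the same reason the planned tests against gene starts, annotation classes, non-coding RNA genes, preset gene lists and the transgene's own loci (nhr-6 and unc-119) were not run. Those of the response element of the receptor family and of GC content were not run because no genome sequence of build WS180 was at hand. From the gene table only the number of protein-coding genes per chromosome was used. The alternatives were the 604 regions with the smallest q-values, merging regions within 1 kb, other distances and segment sizes, leaving out the 10 strongest regions, leaving out regions under 100 bp, leaving out chromosome V, and other expectations per chromosome.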

Results

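Genome-wide binding of NHR-6 was mapped in L2 larvae of C. elegans. NHR-6 is the worm member of the NR4A group of nuclear receptors and is known for its role in development of the spermatheca, the somatic chamber in which oocytes are fertilised. The tagged protein was precipitated through its GFP moiety from 2 replicate worm preparations, and each ChIP library had an input DNA library from the same replicate number. The comparison that the design implies is ChIP against input, which asks where in the genome the receptor binds at this stage. Its result was deposited as 1 combined list of regions, so the values below carry no replicate error and the depth of the libraries is unknown. The libraries include no precipitation from untagged worms or with a control antibody. Signal above input that is unrelated to NHR-6 therefore cannot be told from its binding. A binding region below means a region called over input.

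DNA precipitated through NHR-6::EGFP was called enriched over input in 1209 regions, 1208 on the 6 nuclear chromosomes and 1 on mitochondrial DNA. The nuclear regions covered 633 kb, or 0.637% of the length between chromosome starts and last regions. Their median width was 369 bp, with quartiles of 245 and 619 bp, and widths ran from 1 to 5492 bp. The authors' q-values ranged from 3.48e-33 to just under 0.01, with a median of 0.00186. There were 45 regions with q under 1e-10, 149 between 1e-10 and 1e-05, 305 between 1e-05 and 0.001, and 709 above 0.001, which is 58.7% of the nuclear list.

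The smallest q-values were those of 2 regions and lay nearly 10 orders of magnitude below that of any other region. The first lay on the right part of chromosome V, at positions 14684884 to 14689622 of build WS180, and was 4739 bp wide (q = 3.48e-33). The second lay near the right end of chromosome X, at 16929412 to 16931999, with a width of 2588 bp (q = 4.69e-33). A region of 4404 bp near the left end of chromosome V, at 723835 to 728238, followed with q = 2.59e-23. The next was again on chromosome V, at 6226441 to 6230032 (3592 bp, q = 3.01e-19). The strongest region of chromosome I spanned 9319902 to 9322796 (2895 bp, q = 5.75e-18), and a second strong region, at 9379947 to 9382029, lay on the same part of that chromosome (q = 6.76e-16). The strongest region of chromosome III spanned 10758988 to 10759829 and was narrower, at 842 bp (q = 2.36e-16). Which genes lie at these positions was not analysed here, because the annotation at hand belongs to another genome build.

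Of the 20 strongest regions, 8 lay on chromosome V, 6 on I, 4 on III and 2 on X, and none on II or IV. Besides those above, those of chromosome V began at 5049312 (584 bp, q = 1.53e-17), 14055085 (409 bp), 9343019 (1671 bp), 6099657 (1393 bp) and 10897206 (350 bp). Those of chromosome I began at 14469170 (614 bp, q = 4.23e-17), 4172001 (538 bp), 1834947 (2410 bp) and 7491794 (1466 bp). Those of chromosome III began at 1418700 (1698 bp), 9051224 (2986 bp) and 12598311 (806 bp, q = 1.95e-13), and the remaining region of X began at 1503762 (1385 bp). Their widths ran from 350 to 4739 bp, and 8 of the 20 were wider than 2 kb.

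**Figure D1:**
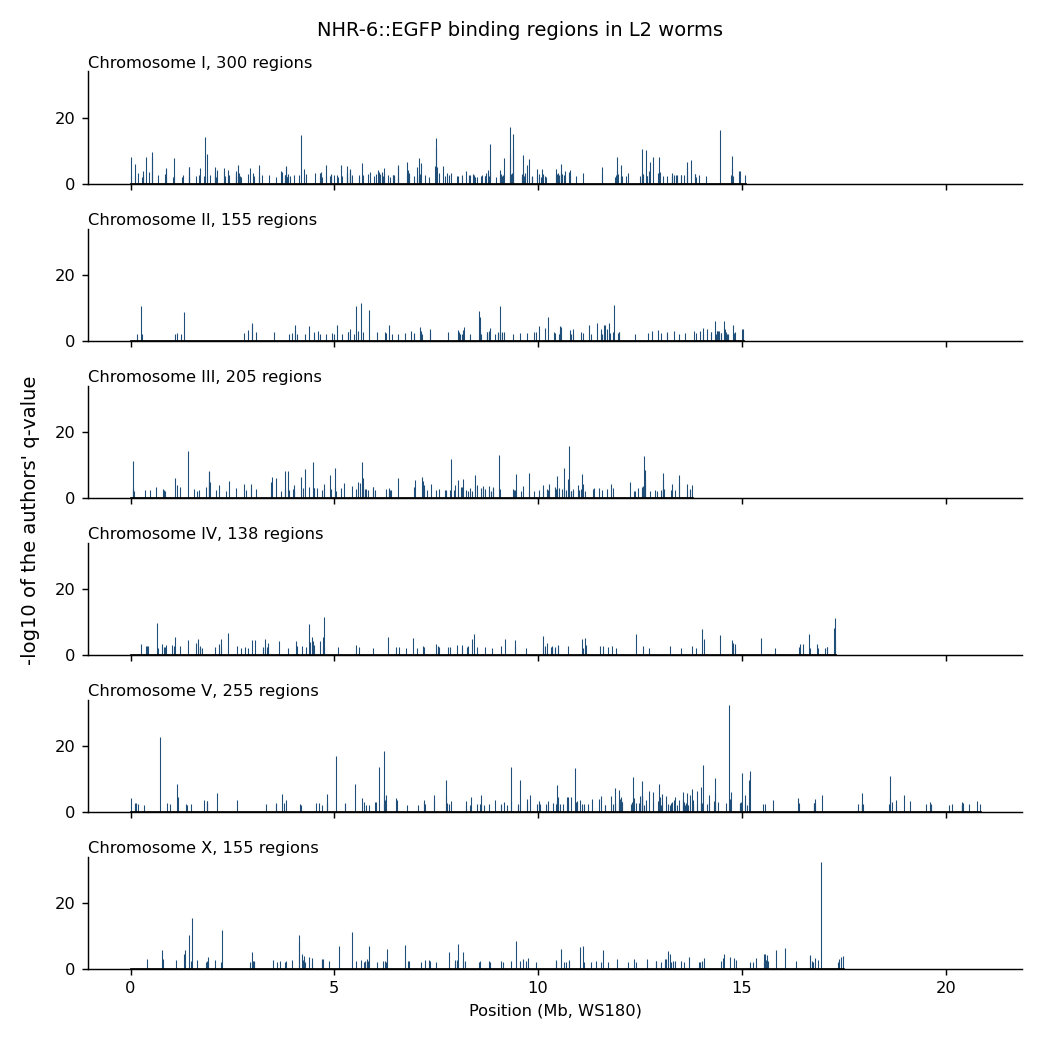
Each vertical line is 1 of the 1208 nuclear binding regions, placed by its midpoint on the horizontal axis (Mb, build WS180) with its height giving −log10 of the authors' q-value; 1 panel per chromosome. The tallest lines stand on chromosomes V and X, and chromosome I, with 300 regions, is the most densely covered.

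Wider regions had smaller q-values. Both values came from the same calls, so the relation describes the list and not occupancy. Across the 1208 regions, which are not independent replicates, Spearman's rho between width and −log10 q was 0.49 and Pearson's r with the logarithm of width was 0.38 (permutation p = 0.0001 for each, the smallest that 10000 permutations can give). Without the 2 regions farthest from the median width, r was 0.39. The median width fell from 1282 bp among regions with q under 1e-10 to 652 bp between 1e-10 and 1e-05, 454 bp between 1e-05 and 0.001, and 293 bp above 0.001. A group of 121 regions was under 100 bp wide, which is shorter than the fragments of a typical ChIP library.

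**Figure D2:**
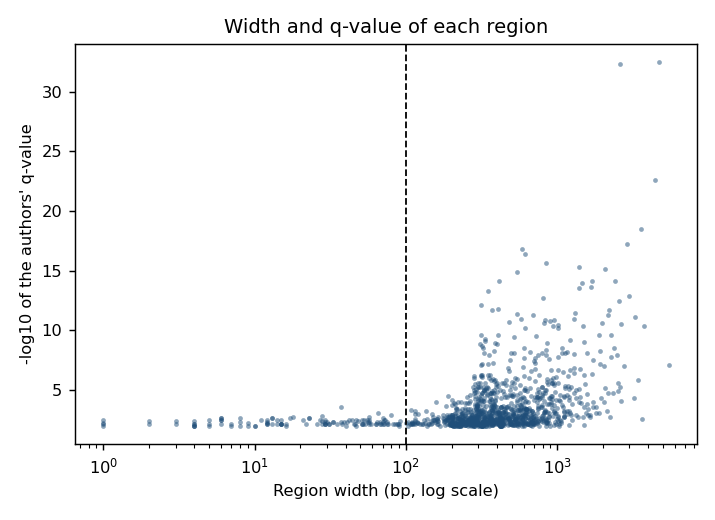
Width of each of the 1208 nuclear regions (horizontal axis, bp, log scale) against −log10 of the authors' q-value (vertical axis); each point is 1 region and the dashed line marks 100 bp. The 121 regions left of the line all lie near the bottom, and 2 of them have q under 0.001.

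Binding regions were unevenly shared among the chromosomes. Chromosome I held 300 regions, a density of 19.9 per Mb (95% Poisson interval 17.7 to 22.3), against 12.1 per Mb over all nuclear chromosomes. This was 1.64 times the number expected from its length (interval 1.48 to 1.81, adjusted p = 1.32e-17, exact binomial test). Chromosome III also held more than expected, with 205 regions, 14.9 per Mb and a ratio of 1.23 (1.08 to 1.39, exact test, adjusted p = 0.00349). Chromosome IV was the sparsest, with 138 regions, 7.98 per Mb and a ratio of 0.657 (0.557 to 0.768, exact test, adjusted p = 3.33e-08).

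Chromosome X held 155 regions, 8.87 per Mb and 0.730 times its expected number (0.626 to 0.845, exact binomial test, adjusted p = 1.58e-05). Chromosome II also held 155, or 10.3 per Mb, with a ratio of 0.849 (0.728 to 0.983, exact test, adjusted p = 0.0325). Chromosome V matched its length within counting error, with 255 regions and a ratio of 1.01 (0.899 to 1.12, exact test, adjusted p = 0.888). Over the 6 chromosomes the departure from length gave a chi-square of 127.6, and the 95% point of the random draws was 11.1 (p = 1e-05, the smallest that 100000 draws can give). Because regions cluster, these intervals are too narrow. In a permutation test that shuffled 500 kb bins between chromosomes, I (adjusted p = 6e-05, the smallest the draws can give over 6 tests), IV (0.00099) and X (0.0169) kept their calls. Chromosomes III (0.0873) and II (0.179) did not. The shuffle treats bins as independent, although density also varied over longer stretches, so its p-values may still be too small. Set against protein-coding gene numbers instead of length, X had a ratio of 0.939 (0.804 to 1.09, adjusted p = 0.426, exact binomial test), and V a ratio of 0.844 (0.753 to 0.940, adjusted p = 0.00191). By the same exact test, I was at 1.72 (adjusted p = 9.54e-21), II at 0.744 (5.49e-05), III at 1.28 (0.000322) and IV at 0.695 (3.42e-06). These gene-number tests again treat regions as independent.

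**Figure D3:**
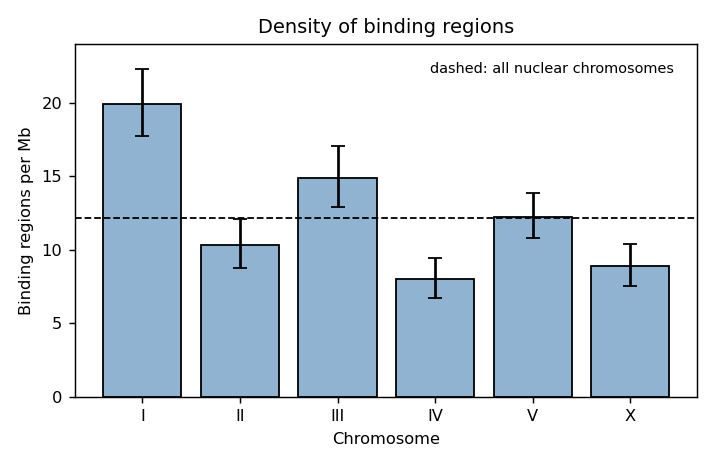
Bars give the number of binding regions per Mb (vertical axis) on each nuclear chromosome (horizontal axis), error bars are exact 95% Poisson intervals, and the dashed line is the density over all nuclear chromosomes, 12.1 per Mb. Chromosome I stands well above the line and III less far above it. V lies almost on it at 12.2 per Mb, and IV and X lie farthest below it.

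On the autosomes, more binding regions than an even spread gives lay in chromosome centres, where genes are denser than on the arms of worm autosomes, but the call did not hold when clustering was kept. The central segment, the middle 33.3% of each chromosome by length, held 432 of 1053 autosomal regions, 41.03% (Clopper-Pearson interval 38.0 to 44.1%), where an even spread would put 33.3% (exact binomial test, adjusted p = 3.82e-07). On X the central segment held 49 of 155 regions, 31.6% (24.4 to 39.6%, exact test, adjusted p = 0.671). The autosomal and X shares differed by Fisher's exact test (two-sided p = 0.0279), which treats regions as independent.

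Chromosome V carried much of the autosomal excess, with 133 of its 255 regions, 52.2%, in the central segment (exact binomial test, adjusted p = 3.17e-09 over the 5 autosomes). The share on chromosome I was 40.3% (exact test, adjusted p = 0.0298). Shares of 38.1% on II, 35.6% on III and 33.3% on IV did not pass (exact tests, adjusted p = 0.388, 0.631 and 1). Without chromosome V the autosomal share was 37.5% (34.1 to 40.9%, exact test, adjusted p = 0.0292 over autosomes and X). When the regions of each chromosome were rotated together, which keeps their clustering, the permutation p was 0.0305 for the autosomes and 0.561 for X, or 0.061 and 0.561 after adjustment over this pair. The rotation was not run for single autosomes or without chromosome V. Those calls rest on exact tests that treat regions as independent.

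Binding regions lay close to one another more often than random placement gave. Another region's midpoint lay within 5 kb of 334 of the 1208 regions, 27.6%, against a mean of 12.4% in uniform placements (95% range 10.02 to 14.98%). The ratio was 2.22 (permutation p = 0.0001, the smallest that 10000 placements can give). Within 2 kb the observed share was 12.003% and the random share 5.18%, and within 10 kb they were 39.5% and 23.2%. Of the 20 strongest regions, 5 had another midpoint within 5 kb. In these pairs the gap between region edges was 239 bp for the region of chromosome III at 9051224, 289 bp for that of chromosome I at 9379947, and over 1 kb for the others, at 7491794 on I and at 6226441 and 9343019 on V. The strongest region of X stood alone, with the nearest midpoint 58.1 kb away, and that near the left end of V was 179 kb from the next. Consecutive regions were never closer than 206 bp, and 67 gaps were of 1 kb or less.

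A difference in strength, measured by q-value alone, between autosomal regions and those of X passed its own test and not the adjusted one. The median −log10 q was 2.76 on the autosomes (1053 regions) and 2.498 on X (155 regions), a difference of 0.27 with a bootstrap interval of −0.01 to 0.35. The permutation p was 0.028, or 0.0561 after adjustment together with a second strength comparison that was chosen after seeing the data. Without the 10 strongest regions the difference was 0.29 (permutation p = 0.0194, unadjusted), and without those under 100 bp it was 0.19 (permutation p = 0.181, unadjusted). Within the autosomes, regions of the central segment and outside it had median −log10 q of 2.77 and 2.75, a difference of 0.02 (interval −0.17 to 0.17, permutation p = 0.782).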

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

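The mitochondrial region was set apart because it lies outside the nuclear comparisons and was nevertheless called above input. It spans positions 12287 to 12635 of the mitochondrial genome, is 349 bp wide and has a q-value of 0.00432, on line 846 of the 1209 in the list. No value per library was used here to show its read depth, and no explanation was tested.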

How the results depend on the processing

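The tests with shuffled bins, gene numbers, extents from first to last region, rotation, 1 Mb windows, without chromosome V, without regions under 100 bp and with skipped ranks kept were chosen after seeing the data. Of 60 results recomputed under an alternative, 49 kept their direction and their side of the threshold or stayed within 1.5 times the count. The list of 1209 regions fell to 604 when only the smaller q-values were kept and 499 at a q-value 10 times below the largest, by construction. The ratio of chromosome II ended its call when regions within 1 kb were merged (0.876) and when 500 kb bins were shuffled (0.842), and that of chromosome III when bins were shuffled (1.22). The autosomal excess in the central segment (ratio 1.23) lost its call when regions were rotated (adjusted permutation p = 0.061), where the ratio is the same by construction. Against protein-coding gene numbers X was no longer low (0.939), and V turned from 1.01 to 0.844, because these chromosomes hold fewer and more genes, respectively, for their length. The ratio of V, which passed no test by length, also lay below 1 after merging (0.970) and from first to last region (0.999). The autosome-to-X difference in strength lost its unadjusted call without regions under 100 bp (0.192), and not without the 10 strongest regions (0.286). The causes of the other changes were not tested. No paired analysis was possible because the deposited list combines the replicates, and for the same reason no replicate could be left out. The alternative without regions within 20 kb of nhr-6 and unc-119 was not run, nor were those of tests that need genes, since the gene table is of another build. Those of tests that need sequence were not run because no genome sequence of the list's build was at hand. Depth is unknown, so how many weaker sites were missed cannot be given.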

Other observations

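The tests of the crowded segments and windows, those of the weak end, repeated values and neighbours for short regions, and that of gene number for chromosome I, were chosen after the results were seen; the ratio of chromosome I among the smallest q-values was planned, and its use as a test of weak calls was chosen after. Among 10 equal segments of each chromosome, the most crowded relative to their own chromosome's mean lay on chromosome V, just right of its middle. The sixth and the seventh segments, from 10421353 to 14589892 of build WS180, held 107 of the chromosome's 255 regions, 41.96%, and 67 of its 134 regions among the 604 with the smallest q-values. In the seventh segment alone there were 59 regions where an even spread gives 25.5, a ratio of 2.31 and a density of 28.3 per Mb. For the test, the excess over the expected number was scaled by the square root of that number. No segment reached as large a scaled excess in 10000 uniform placements over all 60 segments (permutation p = 0.0001, the smallest they can give). Uniform placement treats regions as independent although they cluster, and no test of segments that keeps clustering was run. In regions per Mb the seventh segment was close to the fifth segment of chromosome I, with 27.2. The second segment of chromosome V, from 2084271 to 4168540, held 9. Chromosome II was lopsided: of 3 equal parts, the left held 27 regions and the right 69. Chromosome IV leaned the other way, with 58 on the left and 34 on the right; neither difference was tested. At a finer scale, the most crowded 200 kb windows held 13 regions each, on chromosome I from 3681985 to 3874065 and on chromosome V from 13551473 to 13715833. A window that crowded anywhere in the genome was not beyond uniform placement (permutation p = 0.118).

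Among the 121 regions under 100 bp, only 1.65% had q under 0.001, against 45.7% of the 1087 longer regions (Fisher's exact test, two-sided p = 6.21e-27). Among regions with q of 0.001 or more, 97.5% of the short ones shared their implied p-value (q times rank) with another region, against 63.7% of the longer ones (Fisher's exact test, p = 6.68e-17), and the largest shared set was 30 regions of 1 to 67 bp with q from 0.00668 to 0.00687. Short and longer regions were not matched on q within this range, so the contrast may in part restate that short regions are weak. The short regions were not mainly fragments of neighbouring sites, since 24.8% of them (Clopper-Pearson interval 17.4 to 33.5%) had another region within 5 kb. Their counts per chromosome were not shown to differ from those of longer regions (permutation p = 0.157), which decides nothing. A candidate explanation is that these are places where the same few overlapping reads just passed the caller's threshold; whether the receptor binds there stays open, and no biological explanation was tested because the design has no group that bears on it.

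The excess on chromosome I was set against 3 explanations, none of which accounted for it. Among the 604 regions with the smallest q-values the ratio to length was 1.71 with a lower 95% limit of 1.48, and without regions under 100 bp its lower limit was 1.49, which argues against weak or short calls. Against the share of protein-coding genes the lower limit was 1.56, so gene number does not account for it either. In none of the 3 was the ratio itself (1.71, 1.66 and 1.72) below the 1.64 of the full list by length. The limits treat regions as independent although they cluster, so they are too narrow. The bin shuffle was run only for the full list against length. Differences between chromosomes in the authors' scaling of input, in mappability or in the kind of genes carried were not tested, and no biological explanation was tested.

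The closeness of regions was also larger than either of 2 simple explanations allows on its own. When regions were placed at random within their own 1 Mb window, 13.6% had a neighbour within 5 kb, and the observed 27.6% exceeded the upper end of the random range by 11.4 percentage points, so broad density differences do not suffice. After merging regions within 1 kb the share was 19.4%, still 5.08 points above the random range of uniform placements. Calls split over short distances are thus at most part of it. Merged regions were not compared with placement within 1 Mb windows, so the 2 explanations acting together were not tested. Density differences over less than 1 Mb were not tested either. Binding at several sites around the same genes is a possible explanation that needs a gene annotation of the same build and was not tested; splitting of broad domains over more than 1 kb stays open as well.

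The q-values carry a trace of how the list was made. In 402 pairs of consecutive lines the ratio of q-values was that of 2 consecutive whole-number ranks (within 1e-05 of a whole rank), as for tied p-values multiplied by a constant and divided by rank. In 388 of these pairs, on lines 75 to 1192, the rank equalled the line number. In the remaining 14, from line 1195 to the end, the rank was 45 above it, so the last of the 1209 lines carries rank 1254. The q-value also fell from 1 line to the next 494 times, which a q-value made monotone over ranks would not do.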
